A study of Mus musculus with 5 samples.

How the data were processed

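Hepatocytes of 5 mice (2 LFD, 3 HFD) were profiled by Drop-seq on an Illumina HiSeq instrument, per the labels. Mice and diets were read from the sample titles, and each cell was given to its mouse by the prefix of its column name. All columns of cells were mapped, and 0 were left out. Per the submitters' processing notes, STAR 2.6.0a and the mouse build mm10 were used. The cell filter, the gene annotation, the counting of reads shared between genes, the treatment of strand and of doublets are not given in the sources used here. The raw-read name in the label of HFD mouse 3 has another form than the names of the other mice, from which a separate sequencing run was inferred.

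The deposited table that the authors made for the main measurement holds, for 454 cells and 18018 genes, the natural log of 1 plus the UMIs of a gene per 10000 UMIs of the cell, as the values themselves show. After back-transformation every cell summed to 10000, and 100% of values above 0 were whole multiples of the smallest step of their cell within a tolerance of 0.001, so UMIs were recovered as whole numbers. A second deposited table of the same genes and cells is named for MAGIC, a method that averages values over similar cells, and its values were read as smoothed values on the same natural log scale. Its settings are not given in the sources used here. It was used only to compare with the unsmoothed table.

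Before the data were examined, the groups, tests, gene lists, named-gene rule and most alternatives were fixed. The plan was a quasi-likelihood count model or, for values that are not counts, means on the deposited scale, with limma voom among the alternatives. The deposited unit is a natural log and not a count, and no count model was run, on the recovered UMIs either. Once the values had been found to give whole UMIs, voom was chosen as the main test in place of the planned means, because its weights allow for library sizes that differ as much as these. Recovered UMIs were summed per mouse and tested with limma voom (limma 3.58.1, R 4.3.3) for diet, with trimmed-mean normalization factors, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The mean per mouse of the deposited log values was tested with limma-trend, and its count is printed beside the main one. Genes needed the CPM of 10 UMIs at the median library size (32.4 CPM) in at least 2 mice and 15 UMIs in total, which left 3614 genes for 5 mice and 3670 for 4 mice. Where leaving out mice left 1 mouse in a diet, that lone sample was assumed to vary like the others. No doublet caller was run, and the cells with the highest 5% of UMI totals were left out as an alternative. In 2 groups of 2 and 3 mice, other splits of the samples were not counted.

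Of 29 gene lists fixed beforehand from general knowledge of liver biology, 28 had 5 or more tested members. They were tested with camera of limma with a preset correlation of 0.01, with an estimated correlation, and with fry, and p values were adjusted over the lists. Cells were clustered by the Leiden method (leidenalg 0.10.2) on 15 neighbours and 15 principal components of 2000 variable genes, at resolutions 0.5, 1 and 2. A cluster was called hepatocyte-like where at least 3 hepatocyte markers were found in over 50% of its cells and no other type had 3 markers among its top 10 genes by fold. This departs from the plan, under which markers had to lead a cluster by fold, since clusters that all express hepatocyte markers cannot differ by them. Marker lists were fixed for hepatocytes, macrophages, sinusoidal endothelial cells, stellate cells, cholangiocytes, T or NK cells, B cells, neutrophils, erythroid cells, adipocytes and cycling cells. In the count of cells with 3 or more UMIs of a non-hepatocyte list, the neutrophil and adipocyte lists were left out after the values were seen, as hepatocytes express G0s2, Car3 and Thrsp.

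For the lobule axis, the cells of each mouse were ranked by the log of pericentral over periportal score UMIs, each plus 1, and divided at the median. Sums per mouse and side were tested with limma voom with mouse as a block, for 1652 genes outside the score. The diet interaction was a further term of that model. For shares of cells with a lipid droplet UMI, each cell was thinned to 1728 UMIs (the 25th percentile), and means of mice were compared by a two-sided exact permutation test (SciPy 1.17.1). Intervals of shares are exact 95% binomial (Clopper-Pearson) intervals, and the limit that a count of 0 allows is 3 counts. Fold changes are log2 of HFD over LFD, or of the pericentral over the periportal side.

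The text names the 12 genes of smallest p in each direction among those past the threshold with every HFD mouse beyond every LFD mouse, and from each list the 3 members of smallest p past the threshold or, where there were none, up to 2 of highest CPM. It names 8 genes toward each side of the lobule axis and 5 of the interaction. Predicted gene models were passed over. The same rule was used for the 4 mice without HFD mouse 1. Other members of lists were named after their values were seen, as those of smallest p in their list. Coordinates are of GENCODE vM21 (GRCm38), in which 95 of 95 named genes had 1 gene of that symbol.

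The tests were tried on simulated UMIs for the real genes, mice and library sizes, with 200 genes changed and an assumed dispersion of 0.1. For diet in 5 mice, limma voom recovered 9 of 82 genes changed 2-fold and 49 of 81 changed 4-fold, with 6 false calls among 3382 unchanged genes. For diet in 4 mice it recovered 1.09% and 10.7%, with 0 false calls. For the lobule axis in 5 mice it recovered 33.7% and 96.3%, with 3 false calls. Of 100 random lists, camera gave 1 an unadjusted p under 0.05. Simulated genes were drawn independently of one another, so this could not test the preset correlation of 0.01. In the real lists for diet in 5 mice, estimated correlations ran from -0.0739 (interferon and antigen presentation) to 0.727 (major urinary proteins). The male-biased list had 0.245. Alternatives changed the cell filter, thinning, normalization, gene filter, model, list test, score genes, clustering resolution and the mice included.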

Results

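Single hepatocytes from the livers of 5 male C57BL/6J mice were profiled by Drop-seq, a droplet method that tags each captured mRNA molecule with a cell barcode and a unique molecular identifier (UMI). The mice were littermates, entered the study at 8 weeks of age and were fed a regular diet (LFD, 2 mice) or a high fat diet (HFD, 3 mice) for 12 weeks. The question put by the design was how the hepatocyte transcriptome responds to the high fat diet. The table held 454 cells and 18018 genes, with 1499094 UMIs in all, of which 755918 came from 216 LFD cells and 743176 from 238 HFD cells. LFD mouse 1 gave 132 cells (446868 UMIs) and LFD mouse 2 gave 84 cells (309050 UMIs). HFD mouse 2 gave 208 cells (656803 UMIs), HFD mouse 3 gave 25 cells (58470 UMIs) and HFD mouse 1 gave 5 cells (27903 UMIs). A gene with no UMI could therefore be as high as 4.57 CPM (UMIs of a gene scaled to a total of 1e+06 per mouse) in HFD mouse 2, and as high as 108 CPM in HFD mouse 1, the levels that 3 counts would give. Intervals and such limits cover counting error only.

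HFD mouse 1 stood apart from the other mice. Its barcodes held a median of 6598 UMIs but a median of 636 genes, against 2734 UMIs and 1012 genes in LFD mouse 1. Mitochondrially encoded transcripts made up 8.98% of its UMIs, against 5.10% to 5.63% in the other mice. Mitochondrial ribosomal RNA made up 7.28% of its UMIs, against 3.10% to 4.06% in the other mice, so the excess lay mainly there. Major urinary protein transcripts, which encode abundant secreted pheromone carriers of the male mouse liver, made up 1.43% of its UMIs. The same share was 2.33% in HFD mouse 3, 6.96% in HFD mouse 2, 5.96% in LFD mouse 1 and 6.87% in LFD mouse 2. Values are therefore given for all 5 mice and, as an addition made after the data were seen where it was not already planned, for the 4 mice without HFD mouse 1. A few barcodes of HFD mouse 2 also held few genes for their UMIs, and they remain in the 4 mice.

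**Figure D1:**
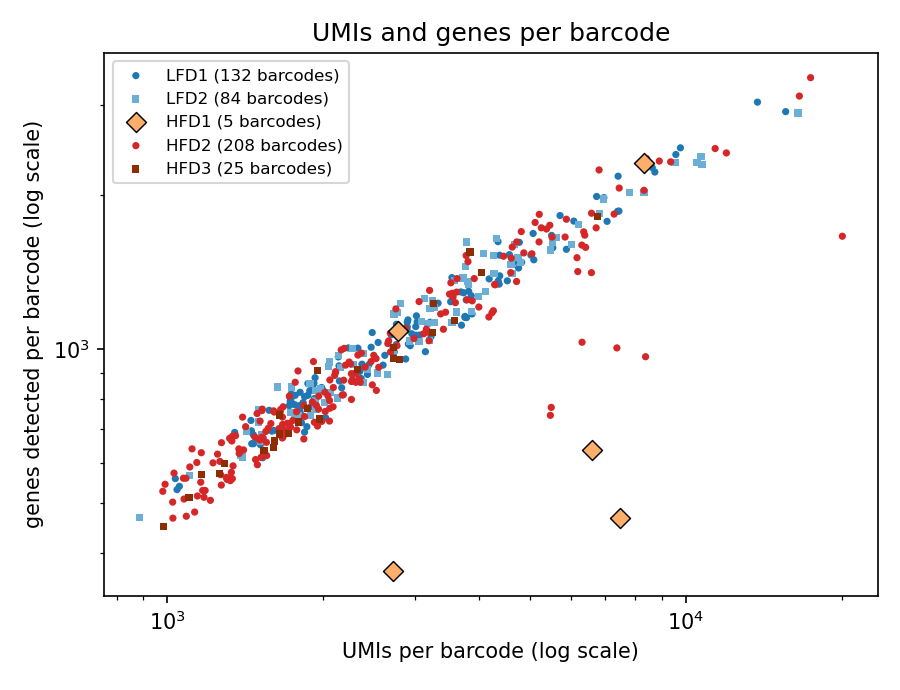
Genes detected (vertical axis, log scale) against UMIs (horizontal axis, log scale) for each of the 454 barcodes, coloured by mouse. Of the 5 barcodes of HFD mouse 1 (large diamonds), 3 lie below the band that most other barcodes form, as do a few barcodes of HFD mouse 2.

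All cells fell into hepatocyte-like clusters. In every cluster, at each of the 3 clustering resolutions tried, 22 or more of the 25 hepatocyte markers were found in over 50% of cells, among the markers Apoa2, an apolipoprotein of HDL, and Fabp1, the liver fatty acid binding protein. Non-hepatocyte clusters held 0 cells in every mouse. Clusters were named as a whole, however, and the smallest at any resolution held 24 cells. A few cells of another type could lie within such clusters, so the 0 sets no limit on their share. LFD mice 1 and 2 had 8 and 4 cells with 3 or more UMIs of a non-hepatocyte marker list. HFD mice 1, 2 and 3 had 3, 9 and 1 such cells. Scattered UMIs of sinusoidal endothelial markers amounted to 1613 CPM in HFD mouse 1, against 29.1 to 45.7 CPM in the other mice. Haemoglobin beta (Hbb-bs), a red blood cell transcript, reached 466 CPM in HFD mouse 1 and 188 CPM in HFD mouse 3, the smallest libraries, against 10.7 CPM in HFD mouse 2 and 2.24 and 3.24 CPM in the LFD mice. Macrophage markers came to 25.9 to 62.7 CPM, stellate cell markers to 15.7 to 51.3 CPM, cholangiocyte markers to 17.1 to 44.8 CPM, T or NK cell markers and B cell markers each to at most 3.24 CPM and cycling cell markers to at most 45.3 CPM over the 5 mice. The neutrophil list (12.9 to 323 CPM) rested on G0s2, the adipocyte list (2975 to 6695 CPM) on Car3 and Thrsp and the erythroid list (89.5 to 609 CPM) in part on Alas2. These 4 genes had UMIs in every mouse, except Thrsp in HFD mouse 1. Different clusters held most cells of the 2 diets, with 186 of 238 HFD cells in one cluster of the lowest resolution and 188 of 216 LFD cells in another, so the diet comparison was made over hepatocyte-like cells of all clusters.

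Several abundant transcripts of xenobiotic metabolism and plasma protein synthesis were lower in HFD mice, and a pair of transcripts of lipid handling was higher. Cyp3a11, the main CYP3A drug-metabolising enzyme of mouse liver, was 3186 ± 57.8 CPM in LFD mice (SD, n = 2) and 238 ± 195 CPM in HFD mice (SD, n = 3), a log2 fold change of -4.25 (SE 0.42, limma adjusted p = 0.000806). Selenbp2, a selenium-binding protein of higher expression in male liver, fell from 989.6 ± 257 to 65.3 ± 99.0 CPM (log2 fold change -5.35, SE 0.68, limma adjusted p = 0.00615), with 0 UMIs in HFD mouse 3, a count that allows up to 51.3 CPM. Cyp4a14, a fatty acid omega-hydroxylase and a target of the nuclear receptor PPAR alpha, rose from 23.9 ± 20.04 to 281 ± 58.2 CPM (log2 fold change 3.72, SE 0.58). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 63.9 ± 24.0 to 587 ± 170.2 CPM (log2 fold change 2.96, SE 0.47). The limma adjusted p was 0.0278 for both.

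The other 4 genes past the threshold were lower in HFD mice. Serpina3k, a secreted serine protease inhibitor and 1 of the most abundant transcripts of the set, fell from 9458 ± 628 to 3184 ± 699 CPM (log2 fold change -1.48, SE 0.24). Cyp2c70, the enzyme that makes the rodent muricholic bile acids, fell from 754 ± 13.04 to 171 ± 38.2 CPM (log2 fold change -2.25, SE 0.37). The limma adjusted p was 0.0278 for both. Orm1, an acute phase plasma protein, fell from 1736 ± 70.7 to 411 ± 213 CPM (log2 fold change -2.12, SE 0.37). Egfr, the epidermal growth factor receptor, fell from 399.5 ± 20.5 to 55.4 ± 22.0 CPM (log2 fold change -2.58, SE 0.46). The limma adjusted p was 0.044 for both. In each of the 8 genes, all 3 HFD mice lay beyond both LFD mice. In HFD mouse 1, however, Egfr rested on 1 UMI, Cyp3a11 on 4, Selenbp2 and Orm1 on 5 each, and Cyp2c70 and Cyp4a14 on 6 each. Apoa4 had 20 UMIs and Serpina3k 74 there, and Egfr had 3 in HFD mouse 3. The SDs of HFD mice thus include counting error. Cyp3a11, Cyp4a14, Cyp2c70, Orm1, Serpina3k and Selenbp2 have close paralogs, and how reads shared between copies were counted is not given in the sources used here.

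**Figure D2:**
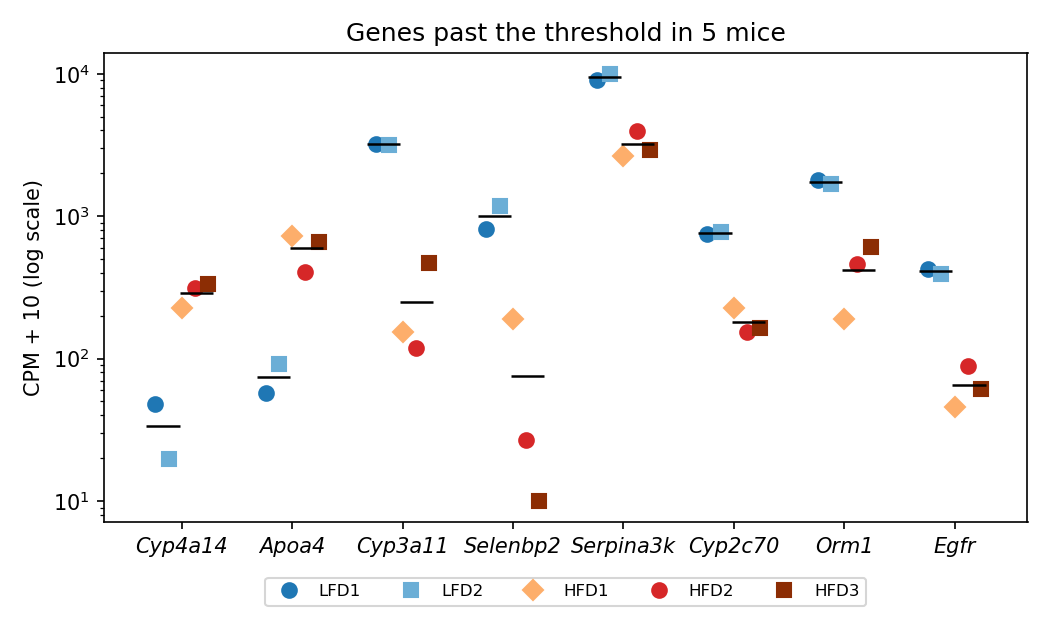
Level of each of the 8 genes past the threshold in each of the 5 mice, in CPM plus 10 on a log scale, with a bar at the mean of each diet. All 3 HFD mice lie above both LFD mice for Cyp4a14 and Apoa4 and below them for the other 6 genes.

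In the GENCODE vM21 annotation of GRCm38 (mm10) all 8 are protein-coding genes. Cyp3a11 lies on chromosome 5 from 145854426 to 145879964, Selenbp2 on chromosome 3 from 94693556 to 94704413, and Cyp4a14 on chromosome 4 from 115486200 to 115496142. Apoa4 lies on chromosome 9 from 46240696 to 46243459, Serpina3k on chromosome 12 from 104338486 to 104346144, and Cyp2c70 on chromosome 19 from 40153353 to 40187333. Orm1 lies on chromosome 4 from 63344560 to 63348163, and Egfr on chromosome 11 from 16752203 to 16918158.

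These 8 were all the genes past an adjusted p of 0.05 among 3614 tested with limma voom on UMIs summed per mouse (2 higher and 6 lower in HFD). An unadjusted p under 0.05 was found for 186 genes, close to the 5% of tested genes that chance gives. In the simulation, 6.48% of unchanged genes had such a p. The median log2 fold change over all tested genes was -0.07. Groups did not overlap for 839 genes (321 higher and 518 lower in HFD), 23.2% of those tested, where chance gives 20%. The mean per mouse of the deposited log values, tested with limma, called 14 genes (1 higher and 13 lower), of which 6 were among the 8. The count rested on which mice were present. Without LFD mouse 1, LFD mouse 2, HFD mouse 2 or HFD mouse 3, limma called 0 genes each time, with 43, 37, 205 and 134 genes at an unadjusted p under 0.05. Without HFD mouse 1 it called 123. HFD mouse 3 appears to come from another sequencing run by the naming of its reads, so the fit without it is also the comparison within 1 run. The count was 45 without the 25 cells that held 3 or more UMIs of a non-hepatocyte marker list. These cells included 3 of the 5 barcodes of HFD mouse 1, and 41 of the 45 genes were also called without that mouse. The count was 2 without the 5% of cells with most UMIs, and 0 with a minimum of 50 UMIs per gene or with limma-trend on summed CPM.

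The male-biased liver genes, a list fixed beforehand of transcripts higher in male than in female liver, were lower in HFD mice. All 20 tested members had log2 fold changes below 0, with a median of -1.84 and with 0 higher and 14 lower when adjusted over the list alone. The camera adjusted p from limma was 3.67e-21, the smallest of the 28 lists tested, and adjusted p = 0.329 with an estimated correlation. Beside Selenbp2 and Egfr, members below the threshold adjusted over the list alone were Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway (-2.18, SE 0.47), Gstp1, a glutathione transferase (-1.79, SE 0.40), and Cyp4a12b, a male-specific fatty acid hydroxylase (-3.09, SE 0.64). These 3 did not pass 0.05 over all genes in 5 mice. The list kept its call without each mouse in turn, with medians from -2.62 (without HFD mouse 2) to -1.13 (without LFD mouse 1). In all, 11 of the 28 lists passed with camera, and 6 without HFD mouse 3, whose separate run is inferred (male-biased genes, major urinary proteins, drug and steroid metabolism, urea cycle, complement and the pericentral list). With an estimated correlation limma called 0 lists. The female-biased list had only 2 tested members, too few for the list test, and Cyp4a14 was 1 of them.

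The major urinary protein family also fell as a set. All 16 tested members had log2 fold changes below 0, with a median of -1.92, and 0 rose and 7 fell when adjusted over the list alone, although 0 passed over all genes in limma. The camera adjusted p was 9.3e-10, and adjusted p = 0.376 with an estimated correlation. The call was kept without each mouse in turn, but the median was -0.94 without HFD mouse 1 and -3.57 without HFD mouse 2. Mup7 was 3245 and 3158 CPM in LFD mice and 35.8, 1189 and 102.6 CPM in HFD mice 1, 2 and 3. The 2 most abundant members did not follow in HFD mouse 2. Mup3 was 39411 CPM there against 32110 and 31532 CPM in LFD mice, and Mup20, the pheromone darcin, was 19019 CPM against 12818 and 14460 CPM. Their log2 fold changes were -0.59 (SE 0.51) and -0.06 (SE 0.34), and both had signs above 0 in the smoothed table. Family members are near-identical in sequence, so values of single members are uncertain.

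Genes of drug and steroid metabolism fell, with 44 of 55 tested members below 0 and a median log2 fold change of -0.50. Over all genes 2 of these passed (Cyp3a11 and Cyp2c70), and 0 rose and 7 fell when adjusted over the list alone. The 7 included Ces2a, a carboxylesterase (-2.91, SE 0.57), and Cyp2f2, a periportal cytochrome (-1.60, SE 0.36). The camera adjusted p was 1.68e-08, and adjusted p = 0.329 with an estimated correlation. HFD mouse 1 stood apart here too, as the members' median of log2(CPM + 10) lay at -1.60 from the LFD mean there, against -0.28 in HFD mouse 2 and -0.22 in HFD mouse 3. The list kept its call without each mouse in turn, but the median log2 fold change was -0.30 without HFD mouse 1, -0.31 and -0.25 without LFD mouse 1 and LFD mouse 2, and -0.82 without HFD mouse 2. Over the 35 members that no other list holds it was -0.20 (camera adjusted p = 0.0357, adjusted p = 0.539 with an estimated correlation).

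Lists of nitrogen handling, plasma protein synthesis, cholesterol and antigen presentation also fell. Of 41 urea cycle and amino acid genes, 34 were below 0 (median -0.57, camera adjusted p = 2.59e-05), and of 43 complement and coagulation genes, 37 were below 0 (median -0.40, camera adjusted p = 2.59e-05). For both, adjusted p = 0.329 with an estimated correlation. Cholesterol synthesis and uptake had 16 of 18 members below 0 (median -0.76, camera adjusted p = 0.00279, adjusted p = 0.532 with an estimated correlation). Interferon and antigen presentation had 9 of 13 below 0 (median -0.42, camera adjusted p = 0.0179, adjusted p = 0.329 with an estimated correlation). No member of these 4 lists passed over all genes or adjusted over the list alone (0 in limma). Members with the smallest unadjusted p were Gnmt, a methyltransferase that consumes S-adenosylmethionine (-1.05, SE 0.27), C8b, a component of the membrane attack complex (-2.43, SE 0.58), Tm7sf2, a sterol reductase (-1.47, SE 0.56), and Ifitm3, an interferon-induced membrane protein (-0.89, SE 0.35). With limma, the interferon list lost its call without members of other lists (adjusted p = 0.0696), and without LFD mouse 1 (adjusted p = 0.0766), LFD mouse 2 (adjusted p = 0.0965), HFD mouse 2 (adjusted p = 0.677) or HFD mouse 3 (adjusted p = 0.287). The cholesterol list lost it without LFD mouse 2 (median -0.29, adjusted p = 0.221), HFD mouse 1 (median -0.31, adjusted p = 0.133) or HFD mouse 3 (adjusted p = 0.0662), and the urea cycle list and the complement list without HFD mouse 2 (adjusted p = 0.0942 and 0.158).

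Lists of PPAR alpha targets and of the immediate early and heat shock response rose as sets in 5 mice. Of 18 PPAR alpha targets, 14 were above 0 (median 0.33, camera adjusted p = 0.0171, adjusted p = 0.665 with an estimated correlation). Cyp4a14 was its 1 member past the threshold over all genes, and 1 rose and 1 fell when adjusted over the list alone, the latter being Cyp4a12a, a male-biased hydroxylase (-2.61, SE 0.63). Of 23 immediate early and heat shock genes, which also respond to cell isolation, 17 were above 0 (median 0.47, camera adjusted p = 0.00236, adjusted p = 0.329 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone in limma. Dusp1, a stress-induced phosphatase, had the smallest p (2.22, SE 0.60). Both calls were lost without HFD mouse 3, where the medians were -0.02 (adjusted p = 0.425) and -0.04 (adjusted p = 0.16), and that of PPAR alpha targets without HFD mouse 2 (adjusted p = 0.509), where the immediate early median was 0.81. Over the 8 PPAR alpha targets that no other list holds, the call was lost as well (adjusted p = 0.128).

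Both zone lists, which name genes expressed near the central or the portal vein, passed toward lower levels in HFD mice, but only with the members that they share with other lists. Without these, the 10 other pericentral genes had a median of -0.24 (camera adjusted p = 0.982), and the 9 other periportal genes one of 0.06 (camera adjusted p = 0.464). The pericentral list had 25 of 35 members below 0 (median -0.41, camera adjusted p = 0.00279, adjusted p = 0.641 with an estimated correlation), and without HFD mouse 1 its median was 0.09 with adjusted p = 0.701, whereas it was -1.02 without HFD mouse 2 and -0.79 without HFD mouse 3. The periportal list had 31 of 48 below 0 (median -0.30, camera adjusted p = 0.0179, adjusted p = 0.329 with an estimated correlation). Its call was lost without LFD mouse 1 (adjusted p = 0.13), LFD mouse 2 (adjusted p = 0.132), HFD mouse 3 (adjusted p = 0.298) or HFD mouse 2 (adjusted p = 0.811). Cyp3a11 was the 1 pericentral member past the threshold over all genes and alone in its list. Apoa4 was the 1 periportal member past the threshold over all genes, and Cyp2f2 and C8b fell when adjusted over the list alone.

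**Figure D3:**
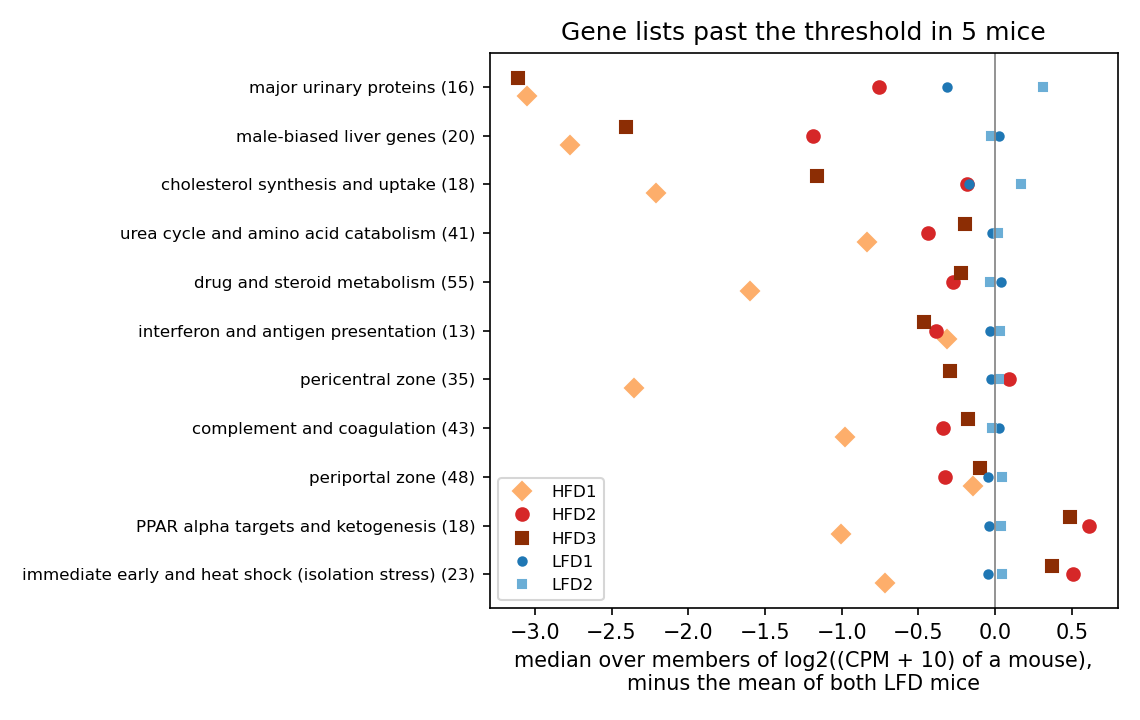
Median over the members of each of the 11 gene lists past the threshold of the log2 of CPM plus 10 in each mouse, minus the mean of both LFD mice, with the number of tested members in brackets. HFD mouse 1 lies below 0 for the PPAR alpha and immediate early lists, whose medians in HFD mice 2 and 3 lie above 0, and it lies far below the other HFD mice for the pericentral list.

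Of the other 17 lists, 0 passed at an adjusted p of 0.05 with camera. Lipid droplet and triglyceride storage came to adjusted p = 0.0936 (median 0.08), fatty acid uptake to 0.0664 (median 0.19), fatty acid oxidation to 0.145 (median 0.13), de novo lipogenesis to 0.744 (median -0.01) and the unfolded protein response to 0.911 (median 0.06). Without LFD mouse 1, LFD mouse 2, HFD mouse 1 or HFD mouse 2 the lipid droplet list passed with camera (medians 0.40, 0.49, 0.21 and 0.96, adjusted p = 0.00309, 0.00285, 0.0236 and 0.00233), as did fatty acid uptake without LFD mouse 2 (median 0.39, adjusted p = 0.00547) or HFD mouse 1 (median 0.32, adjusted p = 0.0184) and fatty acid oxidation without HFD mouse 1. With an estimated correlation, limma called 0 lists in each of these fits, where the smallest adjusted p was 0.395, 0.349, 0.274 and 0.409 without LFD mouse 1, LFD mouse 2, HFD mouse 1 and HFD mouse 2. The gene filter was applied anew in each fit, so list medians do not always cover the same members. The lipid droplet list, for example, had 13 tested members in 5 mice and 12 without HFD mouse 1. The acute phase list came to adjusted p = 0.0664 (median -0.23), although it held Orm1 and Serpina3k. It passed without HFD mouse 1 (median -0.27, adjusted p = 0.0187, adjusted p = 0.274 with an estimated correlation) and without members of other lists (median -0.36, adjusted p = 0.0219, adjusted p = 0.539 with an estimated correlation). Its members did not all move one way, as 2 rose and 2 fell when adjusted over the list alone. With the fry test of limma, which asks whether the members of a list move one way on balance, the acute phase and interferon lists passed (adjusted p = 0.0389 for both).

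Without HFD mouse 1, more genes passed, and transcripts of lipid storage and fatty acid metabolism were among those that rose. The count was 123 genes of 3670 tested (47 higher and 76 lower in HFD), all 8 genes above among them. G0s2, an inhibitor of adipose triglyceride lipase, rose with a log2 fold change of 2.85 (SE 0.49, limma adjusted p = 0.00331). Mgll, monoglyceride lipase, rose by 1.25 and Plin2, a lipid droplet coat protein, by 0.91 (limma adjusted p = 0.0268). Fabp1 rose by 0.71, Fabp2, an intestinal-type fatty acid binding protein, by 1.52, Aldh3a2, a fatty aldehyde dehydrogenase, by 1.91, and Acaa1b, a peroxisomal thiolase, by 0.88, although Acaa1b was 1003 CPM in HFD mouse 1, below both LFD mice (1246 and 1304 CPM). Elovl5, a fatty acid elongase, rose by 1.56 and Fasn, fatty acid synthase, by 0.90. The last 2 and Aldh3a2 had 0 UMIs in HFD mouse 1, which allows up to 108 CPM there, and their 5-mouse limma adjusted p values were 0.989, 0.997 and 0.989.

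The list tests in the 4 mice followed the same genes. Lipid droplet and triglyceride storage (median 0.21, 3 members rose over all genes and 3 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.288 with an estimated correlation) passed. Fatty acid uptake (median 0.32, camera adjusted p = 0.0184, adjusted p = 0.288 with an estimated correlation) passed as well, with 2 members that rose over all genes, and with 5 that rose and 1 that fell adjusted over the list alone. Fatty acid oxidation passed with 21 of 27 members above 0 (median 0.17, camera adjusted p = 0.00745) and the PPAR alpha targets with 13 of 18 above 0 (median 0.63, camera adjusted p = 5.55e-05), and for both adjusted p = 0.274 with an estimated correlation. In these, 1 and 5 members rose over all genes, and 4 and 9 adjusted over the list alone.

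Other genes that rose in the 4 mice were Serpina3m, a protease inhibitor (1.83, limma adjusted p = 0.000417), Abcb4, the canalicular phospholipid transporter (1.37), Dusp1 (2.42), Jun, a subunit of the AP-1 transcription factor (1.31, although 71.7 CPM in HFD mouse 1, below both LFD mice), Ppp1r3b, a glycogen-targeting phosphatase subunit (1.60), Leap2, a secreted peptide of the ghrelin receptor (1.25), Tubb2a, a tubulin (1.92), and Hamp, the iron hormone hepcidin (1.49). The annotated span of Serpina3m (chromosome 12 from 104338486 to 104394257) covers that of Serpina3k, which fell. How reads shared by both were counted is not given in the sources used here. The immediate early list passed with 19 of 24 members above 0 (median 0.53, camera adjusted p = 6.92e-05, adjusted p = 0.274 with an estimated correlation), and 3 rose over all genes and 4 adjusted over the list alone.

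Genes that fell in the 4 mice included Ces2a (-2.62), Cyp2f2 (-1.35), Gstp1 (-1.98), C8b (-1.85), C9, another part of the membrane attack complex (-0.90), Hsd17b2, a steroid dehydrogenase (-1.70), Cyp7b1 (-1.71), Onecut1, a hepatocyte transcription factor (-3.22), Igfbp2, an IGF-binding protein (-1.36), Apoa1, the main protein of HDL (-0.78), Apom, a sphingolipid carrier (-0.82), Gnmt (-0.94), Agxt, an aminotransferase that removes glyoxylate (-0.88), and Cth, of cysteine synthesis (-0.83), each with a limma adjusted p of at most 0.0268. Upp2, a uridine phosphorylase, fell by 3.22 on the log2 scale in the 4 mice, but was 788 CPM in HFD mouse 1 against 273 and 333 CPM in LFD mice, and Apoa1 was likewise higher there (14658 CPM) than in LFD mice (13317 and 14325 CPM). Alas1, the first enzyme of haem synthesis, and Dbp, a clock-controlled transcription factor, passed (-1.82 and -1.86), although HFD mouse 3 (325 and 137 CPM) did not lie below both LFD mice. The male-biased list had 19 of 21 members below 0 (median -1.24, 11 lower over all genes and 15 adjusted over the list alone, camera adjusted p = 4.64e-14, adjusted p = 0.274 with an estimated correlation). Cytosolic ribosomal proteins passed in the 4 mice with 45 of 55 members below 0 (median -0.34, camera adjusted p = 0.000385, adjusted p = 0.531 with an estimated correlation), with 2 members lower over all genes and 2 adjusted over the list alone. With limma-trend in place of voom the count was 14. Leaving out 1 more mouse left a diet with a single mouse, which was assumed to vary like the others. The 123 then became 0 without LFD mouse 1 (541 genes at an unadjusted p under 0.05 with limma), 3 without LFD mouse 2, 182 without HFD mouse 2 (41 of these among the 123) and 200 without HFD mouse 3 (108 of these among the 123).

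Along the lobule axis, the cells of each mouse were divided at the median of a score from 15 pericentral and 19 periportal genes, and both sides were compared within mice. Mup17, a major urinary protein, was higher on the pericentral side in all 5 mice, with 796 ± 14.2 CPM on the periportal and 5582 ± 2143 CPM on the pericentral side of LFD mice (SD, n = 2), and 159 ± 142 and 1029.9 ± 1188 CPM in HFD mice (SD, n = 3). Its log2 fold change was 2.73 (SE 0.26, limma adjusted p = 0.00853). Alb, serum albumin, was higher on the periportal side in all 5 mice, with 48419 ± 4260 against 29968 ± 714 CPM in LFD mice and 60615 ± 13475 against 35792 ± 1254 CPM in HFD mice. Its log2 fold change toward the pericentral side was -0.73 (SE 0.08, limma adjusted p = 0.0115). Mup17 lies on chromosome 4 from 61591929 to 61595871, and Alb on chromosome 5 from 90460897 to 90476602.

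As sets, 18 pericentral list genes outside the score were higher on the pericentral side (camera adjusted p = 9.2e-11, adjusted p = 0.196 with an estimated correlation) and 30 periportal list genes outside the score on the periportal side (camera adjusted p = 1.48e-09, adjusted p = 0.188 with an estimated correlation). Drug and steroid metabolism (camera adjusted p = 0.00163, adjusted p = 0.188 with an estimated correlation) and fatty acid oxidation (camera adjusted p = 0.00338, adjusted p = 0.313 with an estimated correlation) were higher on the pericentral side. Acute phase proteins (camera adjusted p = 0.000132, adjusted p = 0.196 with an estimated correlation), complement and coagulation (camera adjusted p = 0.0086, adjusted p = 0.313 with an estimated correlation) and the mitochondrially encoded genes (camera adjusted p = 3.06e-05, adjusted p = 0.239 with an estimated correlation) were higher on the periportal side. Cytosolic ribosomal proteins passed toward the pericentral side (camera adjusted p = 0.0147) and gluconeogenesis toward the periportal side (camera adjusted p = 0.0431), both with adjusted p = 0.239 with an estimated correlation.

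Of 1652 genes tested along the axis, Mup17 and Alb were the 2 past 0.05 in limma, with 125 genes at an unadjusted p under 0.05. In the 4 mice without HFD mouse 1, which had 2 and 3 cells on its sides, 158 genes passed (80 pericentral and 78 periportal), both among them. The most significant pericentral genes were then Mup17 (2.89), Acaa1b (1.29), Csad, of taurine synthesis (1.98), Aldh1a1, a retinal dehydrogenase (1.39), Mup9 (1.89), Slco1b2, an organic anion uptake transporter (1.28), Gstm1, a glutathione transferase (1.11), and Aldh3a2 (2.87). The most significant periportal genes were Mup20 (-1.26), Alb (-0.71), Hpx, the haem scavenger (-0.87), Trf, transferrin (-0.65), Fgb, fibrinogen beta chain (-0.67), Serpina1e, an alpha-1-antitrypsin (-0.82), mt-Cytb, mitochondrial cytochrome b (-0.70), and Sfxn1, a mitochondrial serine transporter (-1.59). Each had a limma adjusted p of at most 1.6e-05. All 4 mice shared the direction, except that Mup9 was higher in 3 of 4 and Serpina1e was lower in 3 of 4. The 2 calls of the 5 mice became 0 without LFD mouse 1, LFD mouse 2 or HFD mouse 3 (68, 68 and 117 genes at an unadjusted p under 0.05) and 1 without HFD mouse 2.

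Whether the diet response differed along the axis was tested as an interaction. In 5 mice limma called 0 of 1652 genes, with 8 at an unadjusted p under 0.05. These 8 lie far below the share that chance gives. The absence of calls therefore does not show that the response was alike on both sides. Without HFD mouse 1, limma called 1 gene, Mup11, another major urinary protein, with 92 of 1935 genes at an unadjusted p under 0.05. The pericentral excess of Mup11 was greater in HFD mice by 2.12 on the log2 scale (SE 0.22, limma adjusted p = 0.00183). Mup11 was 4014 and 7613 CPM on the periportal and 5212 and 8132 CPM on the pericentral side of the LFD mice. It was 905 and 4855 CPM in HFD mouse 2 and 117 and 579 CPM in HFD mouse 3 in the same order of sides. With HFD mouse 1 included, in which Mup11 had 0 UMIs, the interaction was 1.72 with a limma adjusted p = 0.976.

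Cells with a lipid droplet transcript made up a higher mean share in HFD mice, by a difference that the test could not call. After each cell was thinned to 1728 UMIs, which kept 341 of 454 cells, 39.5% ± 2.40 of cells in LFD mice (SD, n = 2) and 72.9% ± 25.3 in HFD mice (SD, n = 3) held a UMI of Cidec, Cidea, Plin2, Plin4, Plin5, G0s2 or Mogat1. The share rested on Plin2 and G0s2, since Cidea and Plin4 were found in 0 cells, Cidec in 3 cells and Mogat1 in 1 cell of all mice. The shares were 41.2% and 37.8% in LFD mice 1 and 2, and 100% of 5 cells, 68.7% of 134 cells and 7 of 14 cells in HFD mice 1, 2 and 3. The exact 95% binomial intervals were 32.1% to 50.8% for LFD mouse 1, 26.8% to 49.9% for LFD mouse 2, 47.8% to 100% for HFD mouse 1, 60.1% to 76.4% for HFD mouse 2 and 23.0% to 76.96% for HFD mouse 3. A two-sided exact permutation test gave p = 0.2, the smallest that 2 mice against 3 can reach, and 0.6 after Benjamini-Hochberg adjustment over the gene tests. Plin2 alone was found in 30.3% ± 3.08 of LFD and 58.5% ± 18.7 of HFD cells (exact p = 0.2), and G0s2 in 8.81% ± 8.63 and 33.3% ± 16.7 (exact p = 0.4). Plin5, a droplet protein at mitochondrial contacts, was found in 6.69% ± 2.01 of LFD and 1.99% ± 3.45 of HFD cells (exact p = 0.4). Without thinning the 7-gene shares were 54.1% ± 0.689 and 81.1% ± 18.1. With thinning, the difference between the diets was 33.4 points in 5 mice and 19.8 points without HFD mouse 1. Free RNA in droplets can add such UMIs, and no cluster of another cell type was found to give its background.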

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

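The tests of the male-biased genes and of HFD mouse 1 below were chosen only after the result was seen, whereas the leaving out of each mouse was planned. The pericentral excess of Mup11, a major urinary protein, differed between diets by 2.12 on the log2 scale without HFD mouse 1, by the interaction term of limma (adjusted p = 0.00183). With all 5 mice the limma adjusted p was 0.976 for 1.72. Without HFD mouse 3 as well the value was 2.13, but it then rested on a single HFD mouse. Reads can be shared between the near-identical genes of this family, so which family member carried the shift is uncertain.

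Lower male-biased liver genes in HFD mice formed the list result with the smallest p, with a median log2 fold change of -1.84 in 5 mice. A change in the zone makeup of the sampled cells would move pericentral and periportal members in opposite directions. The 6 members with a pericentral estimate had a median of -1.51 and the 10 with a periportal estimate one of -1.89, all below 0. Members were assigned by the sign of that estimate alone, however. Along the axis, 0 of the 16 passed over all genes and 2 adjusted over the list alone. The split therefore cannot decide whether zone makeup underlies the pattern. HFD mouse 3, whose separate run is only inferred from its read name, is not needed for the pattern. The median without that mouse was -1.75 with 19 of 21 members below 0. The 5 barcodes of HFD mouse 1 are not needed either, as the median without that mouse was -1.24, also with 19 of 21 members below 0. A response of growth hormone or androgen dependent transcription to the diet may underlie the pattern and stays untested, as do differences between the animals or their dissociation that go with the diet in so few mice.

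The endothelial marker UMIs in HFD mouse 1 (45 UMIs, 1613 CPM) do not look like those of endothelial cells. Only 4 of 18 endothelial markers had a UMI there, and Clec4g, Stab2, Dnase1l3 and Igfbp7, abundant in sinusoidal cells, had 0. Kdr held 26 of the UMIs, 21 of them in 1 barcode, and all 11 UMIs of Egfl7 were in 1 barcode. In the 5 barcodes, 126 genes had 10 or more UMIs in 1 barcode and at most 1 in each of the others, against at most 7 in 1000 draws of 5 LFD barcodes of like UMI total, and among these were Dhx40 (70 UMIs) and Sdf2 (65 UMIs). Molecules counted many times in single barcodes, for example by errors in identifiers, would give such a pattern. Of the endothelial markers, however, only Egfl7 met this rule. Kdr had more than 1 UMI in another barcode, and Fcgr2b and Mrc1 had 4 UMIs each. Whether such counting gave the UMIs of Kdr, Fcgr2b and Mrc1 stays open. Apart from endothelial RNA, no biological explanation was tested. The count of such genes was made for HFD mouse 1 alone. Some barcodes of HFD mouse 2 also held few genes for their UMIs, such as 743 genes at 5483 UMIs and 1662 genes at 20046 UMIs. A barcode of LFD mouse 2 with 5488 UMIs held 1562 genes. Leaving out HFD mouse 1 may thus not remove all barcodes of this kind.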

How the results depend on the processing

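The fits without 1 mouse and most other settings were planned, whereas the tests without HFD mouse 1 in combination with other changes, limma-trend on smoothed means or on summed CPM with a pseudocount of 1, limma-trend as the test of the planned deposited means, quality weights and the removal of marked cells were chosen only after the result was seen. The 8 diet genes kept their direction in all 16 settings planned for each gene, but each stayed past the threshold in only 5 to 9 of them, and Cyp3a11 had log2 fold changes from -4.61 to -3.32 and Apoa4 from 2.68 to 3.54. The count of 8 was 7 or 8 with median-ratio size factors, thinned cells, all barcodes, no major urinary protein or mitochondrial genes in the library size, or without the 25% of cells with fewest UMIs. It was 2 without the 5% of cells with most UMIs per mouse, 2 with no gene filter (11512 genes tested, 463 at an unadjusted p under 0.05), and with limma 0 with 50 UMIs in total, with mean per-cell CPM, and with summed CPM at a pseudocount of 1 or 10 (123, 48, 44 and 66 genes at an unadjusted p under 0.05). The last 3 also moved the median log2 fold change of all genes from -0.07 to -0.52, -0.53 and -0.37. It rose to 14 with deposited log means, 45 without cells with 3 or more UMIs of a non-hepatocyte list, 51 with quality weights and 2556 with smoothed means. Leaving out mice gave 0 to 200 genes, with 117 without HFD mouse 1 and median-ratio factors and 14 without it under limma-trend. Lists past the threshold numbered 11, 8 without shared members (PPAR alpha, interferon, pericentral and periportal lists lost, acute phase gained), 6 to 14 without 1 mouse, 0 with an estimated correlation and 2 with fry. The periportal list median ran from -0.34 to 0.00 without 1 mouse and turned in sign without HFD mouse 2 (0.0042). The lobule axis gave 17 genes with outer tertiles of cells, 3 with Cyp2e1 and Cyp2f2 alone, 5 with thinned cells, 1 with no gene filter and 0 to 197 without mice, and the interaction 0 to 7 (7 only with HFD mouse 2 as the single HFD mouse). Smoothed means turned the sign of Acaa2 (-0.0302), Hspa8 (-0.0218), Mup20 (0.0788) and Mup3 (0.0399), and Mup20 ran from -1.05 to 0.51 when mice were left out, above 0 without HFD mouse 1 and HFD mouse 3. The cause of these turns was not tested. The difference in non-hepatocyte share moved from 0 to 17.4 points when cells with 3 or more marker UMIs were counted, as 60.0% of the 5 cells of HFD mouse 1 were (exact p = 1.0). The lipid droplet difference of 33.4 points was 27.1 points without thinning and 19.8 to 44.8 points without 1 mouse. Between the diets, the differences of replicate 1 from replicate 2 had a correlation of 0.0599 across 2953 genes. As this value rests on the 5 barcodes of HFD mouse 1, it cannot tell whether replicate numbers paired the mice. With a replicate block on the numbers in 4 mice, limma called 19 genes (338 at an unadjusted p under 0.05) and 5 lists. The same 4 mice without the block gave 0 genes (134 at an unadjusted p under 0.05). The planned DESeq2 and edgeR were not run, and limma voom took their place on the recovered UMIs. Of 82 genes with a simulated 2-fold change, limma recovered 9 in 5 mice, at an assumed dispersion of 0.1 that was not estimated from these mice. In 4 mice the simulation recovered 1.09% of 2-fold changes, whereas the real fit called smaller ones, such as Fabp1 (0.71). The simulated recovery may therefore not carry over to these data.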

Other observations

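Of the tests here, those of diet within each side of the lobule, of mouse pairs and of the smoothed table were chosen only after the result was seen, and the list tests in all mice and the fit without HFD mouse 1 were planned. Diet differences were also present within each side of the lobule axis. On the periportal side of 5 mice, limma called 6 genes higher and 18 lower in HFD among 2232 tested, and on the pericentral side 0 higher and 2 lower among 1848, with 170 and 65 genes at an unadjusted p under 0.05. Without HFD mouse 1, which had 2 and 3 cells on its sides, the counts were 20 higher and 36 lower on the periportal side and 2 higher and 12 lower on the pericentral side, with 375 and 358 genes at an unadjusted p under 0.05. Male-biased genes were lower as a set on both sides, with medians of -1.52 on the periportal side (camera adjusted p = 7.21e-16, adjusted p = 0.319 with an estimated correlation) and -2.07 on the pericentral side (camera adjusted p = 3.41e-16, adjusted p = 0.614 with an estimated correlation). Without HFD mouse 1 these medians were -1.48 (camera adjusted p = 1.27e-11, adjusted p = 0.228 with an estimated correlation) and -1.21 (camera adjusted p = 1.07e-06, adjusted p = 0.501 with an estimated correlation). Drug and steroid genes had medians of -0.46 (camera adjusted p = 1.42e-11, adjusted p = 0.319 with an estimated correlation) and -0.61 (camera adjusted p = 3.16e-05, adjusted p = 0.614 with an estimated correlation), and without HFD mouse 1 of -0.51 (camera adjusted p = 2.61e-10, adjusted p = 0.228 with an estimated correlation) and -0.21 (camera adjusted p = 0.000242, adjusted p = 0.452 with an estimated correlation). For both lists the side with the lower median thus turned with that mouse. Except for the interaction test, the difference between the sides was not tested.

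Other lists, among them those of energy metabolism and protein turnover, did not pass with camera in 5 mice. Nuclear-encoded oxidative phosphorylation genes had a median of -0.24 (adjusted p = 0.0687), ribosomal proteins -0.19 (adjusted p = 0.145), apolipoproteins 0.12 (adjusted p = 0.152), hepatokines -0.23 (adjusted p = 0.194), the proteasome -0.09, the circadian clock -0.33 and iron and haem genes 0.10 (adjusted p = 0.524 for each of these 3), gluconeogenesis -0.06 (adjusted p = 0.722), mitochondrially encoded genes -0.14 and bile acid genes 0.04 (adjusted p = 0.744 for both) and antioxidant genes -0.16 (adjusted p = 0.761). Some of these passed when a mouse was left out, with 0 lists called by an estimated correlation there. The apolipoproteins passed without LFD mouse 1 (median 0.23, adjusted p = 0.0107, adjusted p = 0.395 with an estimated correlation) and HFD mouse 2 (median 0.17, adjusted p = 0.0383, adjusted p = 0.502 with an estimated correlation), and iron and haem genes without HFD mouse 2 (median 0.51, adjusted p = 0.0036, adjusted p = 0.409 with an estimated correlation). The ribosomal proteins passed without LFD mouse 2 (median -0.36, adjusted p = 0.00249, adjusted p = 0.446 with an estimated correlation) and, as given above, HFD mouse 1. The bile acid test pointed down although its median was above 0, and that of de novo lipogenesis up although its median was below 0. In the 4 mice without HFD mouse 1, Zfp36l1, an mRNA-destabilising protein (1.31), and Gclc, of glutathione synthesis (0.89), were higher in HFD. H2-Q10, a secreted class I molecule (-0.55), Cyp2c29, a pericentral cytochrome (-0.92), C2, a complement protease (-1.56), Ahsg, fetuin A (-0.54, although 6451 CPM in HFD mouse 1 against 4675 and 3941 CPM in LFD mice), and the ribosomal proteins Rps14 (-0.80) and Rpl14 (-1.02) were lower, each with a limma adjusted p of at most 0.0483. Hspa8, a constitutive chaperone, was 2545 CPM in HFD mouse 1 against 174 to 239 CPM in the other mice, and Acaa2, a mitochondrial thiolase, 4408 CPM against 1096 to 1317 CPM. Pairs of mice that share no animal moved alike for most of the genes that differed at least 2-fold in one pair, with the same sign for 50 of 64 genes (HFD mouse 2 against LFD mouse 1, then HFD mouse 3 against LFD mouse 2) and 61 of 76 genes with the LFD mice exchanged. Over the 1206 genes compared, the Spearman correlation of these pairs was only 0.288 and 0.334. With HFD mouse 1 in place of HFD mouse 3 it was 0.159 and 0.221, although 51 of 64 and 60 of 76 genes had the same sign. The share of same signs over all 1206 genes is not given here.

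The smoothed table gave 2556 genes past the threshold with limma, against 14 from the unsmoothed means of the same 3614 genes. Smoothing reduced the spread between mice of a diet to a median ratio of 0.0140 of its unsmoothed size, but the diet difference only to 0.0762. Cyp3a11 had mean natural log values of 3.29 and 3.26 in LFD mice and 0.873, 0.270 and 0.498 in HFD mice before smoothing, and 1.91 and 1.91 against 1.59, 1.61 and 1.64 after it. Of simulated genes with differences between mice (an assumed SD of 0.5 on the natural log scale) but none between diets, 87.1% were called after averaging over similar cells, and 0% before it. Averaging of this kind may thus give many of the calls, and which of them reflect the diet stays open.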
